A study of Rattus norvegicus with 6 samples.

How the data were processed

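Gene expression was measured on single-colour Illumina arrays in primordial follicles of the rat, the resting follicles in which an oocyte is enclosed by flat pregranulosa cells. Total RNA was labelled as biotinylated cRNA with the Illumina TotalPrep kit, per the labels' protocols. Each of the 6 arrays carried RNA of 1 pooled sample, and 3 samples came from aged and 3 from immature rats. Per the series' design text, each sample pooled follicles from several isolations of many ovaries, so an array measures an average over animals. Nothing in the labels says whether the 3 pools of a group shared animals. The p-values therefore measure the spread between these pooled samples, which may be technical.

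The values deposited by the authors are taken here as log2 values. They cover 45281 probes and are rounded to 2 decimals. The median of each probe over the 6 arrays is within 0.005 of 0, apart from 4 probes, so each value is a deviation from the probe's own median and the signal level of a probe is not in the table. The median of each array is also 0. The background correction, the normalization between arrays, the software, the detection filter and the array design are not given in the sources used here, and neither is whether the probes were designed for rat sequence. The number of probes resembles that of a mouse whole-genome array, which could not be checked here, so a hybridization of rat RNA to mouse probes is not excluded. A probe's signal would then depend also on how well the rat transcript matches it. The log base is not given either. The widest range within a probe is 7.47 units, while the log10 of the largest value of a 16-bit scanner is 4.82, so log10 is excluded. The natural log is not excluded, and log2 is assumed throughout. With natural logs, every fold given here would be larger. The direction could not be set against scanner values, and a higher value is read as a higher signal, as is usual for a single-colour array. Centring subtracts the same number from all arrays of a probe and leaves differences between arrays unchanged, except for rounding.

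Differences were computed with limma 3.58.1 in R 4.3.3 on the values as deposited. A linear model with 1 term for the group was fitted to each probe, aged minus immature, with variances moderated by eBayes and a mean-variance trend. P-values were adjusted over all 45281 probes by the Benjamini-Hochberg method, and a probe was called changed at an adjusted p under 0.05. The test, the threshold and the alternatives for the counts of changed probes were fixed before the data were examined, when it was not known that the values were centred. A mean of centred values is not a signal level, so the trend has no level to follow, and the fit without a trend is given beside it where the call differs. Signal detection, background and dim probes could not be assessed for the same reason, and the planned filters on dim probes were not run. The precision is limited by the number of arrays. The median spread of a probe within a group was 0.070 (SD, log2 units), and the median standard error of a log2 fold change was 0.061. Standard errors given here are moderated, so they draw on the spread of other probes as well as a probe's own.

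No gene is named. The table does not pair its probe numbers with genes, and 0 rows of the rat gene table used as a reference hold such a probe number. The 25 gene lists that had been fixed, for oocyte, granulosa and other ovarian cell types, DNA repair, apoptosis and further pathways, were therefore not tested, and neither were planned values of single genes. The rule for named items took the largest changes among called probes whose 3 aged and 3 immature values did not overlap. Its condition on the signal level could not be applied, and it was shortened to the 2 probes with the largest change each way, named by probe number.

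The model was tested on simulated data made from the real probes' spreads, centred and rounded like the deposited values, with 200 of 45281 probes changed for the comparison of aged with immature. It recovered 10 of 50 probes changed by 0.25 on the log2 scale and 38 of 50 changed by 0.5. It recovered 50 of 50 changed by 1 and 48 of 50 changed by 2, with 11 false calls. Far fewer probes were changed here than the 3982 called in the data. The cut-off after adjustment was therefore stricter in the simulation, and its rates and false calls do not carry over to the data. Alternatives were quantile and cyclic loess normalization of the deposited values, a shift of each array to a median of 0, no trend, array weights, a test per probe without moderation, the replicate number as a block, a 2-fold threshold and leaving out each array. Noise within the last decimal, leaving out each array in a fit without a trend, and all alternatives for the correlation between replicates and for the separate counts of 2-fold changes were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.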

Results

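The study set primordial follicles of aged rats against those of immature rats, to describe how gene expression in the resting follicle pool differs with age. The table held 45281 probes measured on 3 arrays of aged and 3 arrays of immature follicles, each array from a separate pooled sample. Values were deviations from each probe's median over the 6 arrays. They were taken as log2, which the sources do not state, and every fold given here rests on that. The standard deviation over all probes of an array lay between 0.126 in immature replicate 2 and 0.144 in aged replicate 1. Probe numbers were not paired with genes in the files used here, so results are given for probes, whose match to rat transcripts is not known here, and no oocyte, granulosa or pathway gene could be read out.

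Arrays separated by age group. The first principal component held 73.3% of the variance over all probes and the second 7.70%. Aged arrays scored 25.5, 23.0 and 23.2 on the first component for replicates 1, 2 and 3, and immature arrays scored -25.4, -23.3 and -23.0. On the second component, aged replicate 1 scored 13.6 and aged replicate 3 scored -11.7, with the other arrays between them. Pearson correlations across probes were 0.60 to 0.65 between arrays of the same group and -0.72 to -0.66 between arrays of different groups. Probes are not independent replicates, and these correlations were given no test. Centring on the probe median lowers correlations between arrays, and simulated values without a group difference, centred in the same way, gave a mean correlation of -0.14.

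**Figure D1:**
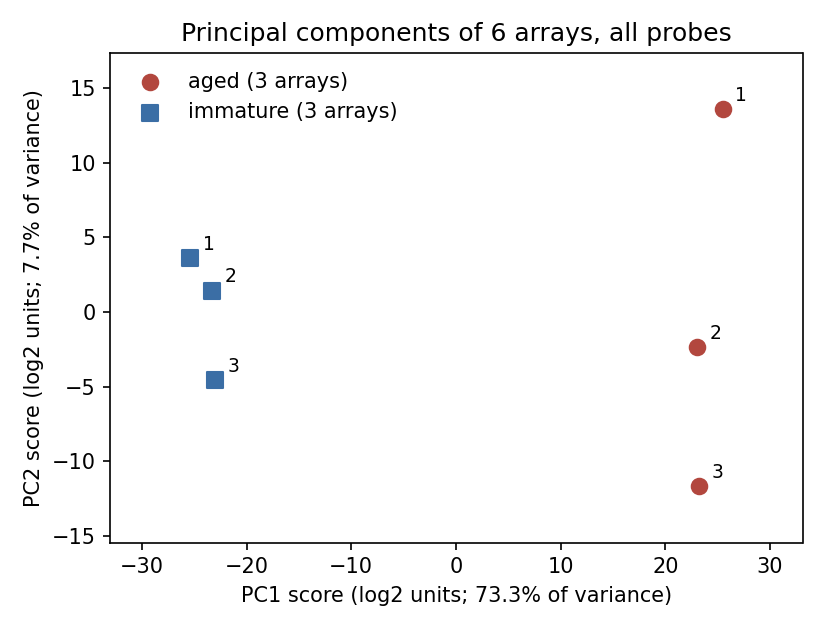
Scores of the 6 arrays on the first (x axis, 73.3% of variance) and second (y axis, 7.70%) principal components of all 45281 probes, in log2 units. Each point is 1 array, numbered by replicate, with aged arrays as red circles and immature arrays as blue squares. The 3 aged arrays lie at 23.0 or more and the 3 immature arrays at -23.0 or less on the first component.

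Of the 45281 probes, 3982 (8.79%) differed between aged and immature follicles in limma's moderated test at an adjusted p under 0.05. Of these, 1698 were higher in aged follicles and 2284 were lower. At an unadjusted p under 0.05, 6983 probes differed. The 3 aged values and the 3 immature values did not overlap in 3875 of the 3982 called probes. Over all probes the groups did not overlap in 7808, or 17.2%, where chance gives 10% for 3 arrays against 3. A test per probe without moderation called fewer probes, 1226, of which 577 were higher and 649 lower.

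Most differences were small. The median size of the log2 fold change was 0.42 among the called probes and 0.05 among all probes, and 90.7% of all probes changed by less than 0.2. The smallest called change was 0.18.

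The direction of the called changes differed with their size. Among the 3571 called probes that changed by less than 2-fold, 2146 (60.1%) were lower and 1425 were higher in aged follicles. Called changes under 0.2 on the log2 scale were few and more even, with 61 higher and 47 lower. Only 0.263% of all probes in that range were called, and of all of them 21194 were higher and 19876 lower. Over all probes that changed by less than 2-fold, called or not, 22709 were higher and 22156 lower. Among the 411 called probes that changed by at least 2-fold, 273 (66.4%) were higher and 138 were lower. At a change of at least 4-fold, 47 probes were higher and 19 were lower. Quantile normalization of the deposited values, which gives all arrays 1 distribution and so evens out the tails of these centred values by construction, gave 233 higher and 187 lower at 2-fold or more, or 55.5% higher. Cyclic loess gave 258 higher and 137 lower, or 65.3% higher, but it follows means of centred values, which are not signal levels.

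**Figure D2:**
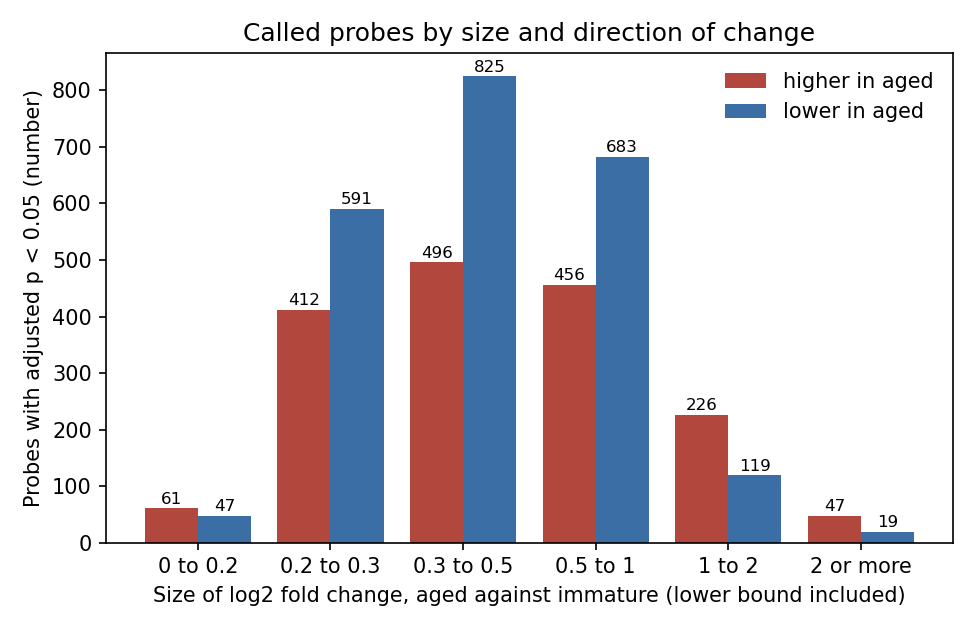
Number of probes with an adjusted p under 0.05 (y axis) by the size of the log2 fold change between aged and immature follicles (x axis), for probes higher in aged (red) and lower in aged (blue). Lower probes outnumber higher ones from 0.2 to 1, with 825 against 496 between 0.3 and 0.5, and higher probes outnumber lower ones from 1 upward, with 226 against 119 between 1 and 2.

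The largest increase was at probe ILMN_3105563, with a mean centred log2 value of 3.60 ± 0.081 (SD, n = 3) in aged and -3.66 ± 0.145 (SD, n = 3) in immature follicles. Its log2 fold change was 7.25 with a moderated standard error of 0.070, a 152.6-fold difference, with an adjusted p of 1.36e-23 in limma's test. Probe ILMN_1233840 followed at 2.99 ± 0.116 (SD, n = 3) in aged and -2.93 ± 0.053 (SD, n = 3) in immature follicles, a 60.7-fold difference with a limma adjusted p of 1.31e-22. The largest decrease was at probe ILMN_1226762, which had -2.52 ± 0.403 (SD, n = 3) in aged and 2.20 ± 0.225 (SD, n = 3) in immature follicles. This was a 26.4-fold lower value in aged follicles, with a log2 fold change of -4.72, a moderated standard error of 0.159 and a limma adjusted p of 1.35e-14. Probe ILMN_1256343 had -1.67 ± 0.242 (SD, n = 3) in aged and 1.53 ± 0.120 (SD, n = 3) in immature follicles, a 9.21-fold lower value with a limma adjusted p of 1.03e-15. After quantile normalization of the deposited values the folds were 63.5 for ILMN_3105563, 28.1 for ILMN_1233840, 63.5 for ILMN_1226762 and 16.5 for ILMN_1256343, in the same directions. That setting gives the highest and lowest ranks of all arrays the same values by construction, and with cyclic loess the folds were 153.2, 60.5, 17.9 and 8.58 in the same order. All of these differences exceeded the spread between replicates many times over. The test per probe without moderation, which uses only a probe's own spread, gave larger adjusted p-values. They were 0.00326 for ILMN_3105563 and ILMN_1233840, 0.0123 for ILMN_1226762 and 0.0113 for ILMN_1256343. When an array was left out in the fit with a trend, ILMN_3105563 lost its call without each of the 6 arrays and ILMN_1233840 without each array except aged replicate 3. ILMN_1226762 lost its call without each immature array, and ILMN_1256343 kept its call throughout. The folds in the fits that lost the call stayed at 145.2 to 160.5 for ILMN_3105563, 58.5 to 62.0 for ILMN_1233840 and 24.1 to 27.7 for ILMN_1226762. In the fit without a trend, every one of these probes kept its call without each array, and the highest adjusted p was 5.48e-11.

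**Figure D3:**
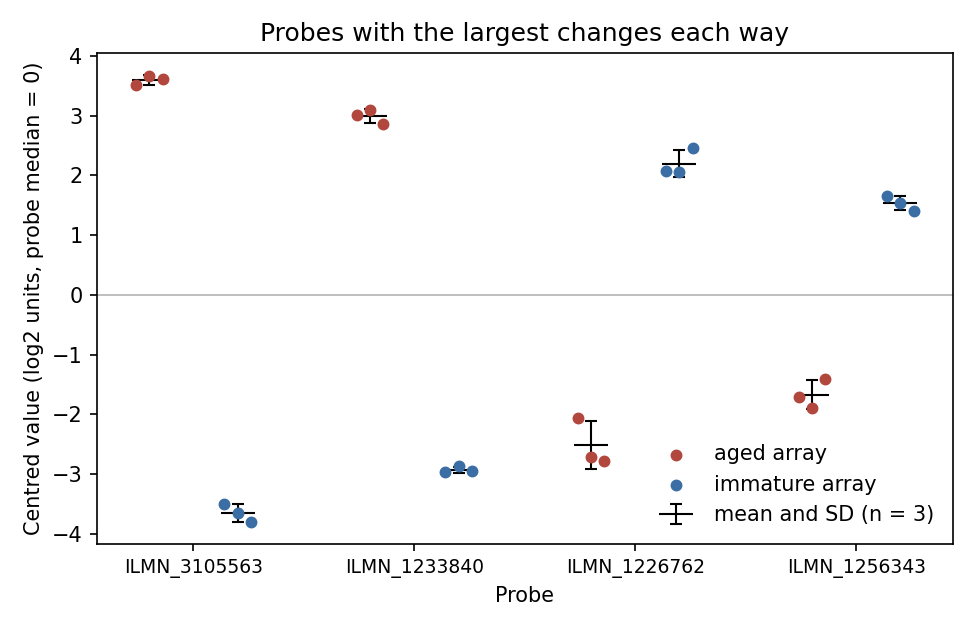
Centred log2 values (y axis, probe median at 0) of the 2 probes with the largest increase and the 2 with the largest decrease in aged follicles (x axis). Points are single arrays, aged in red and immature in blue, and bars are the mean and SD of 3 arrays. The aged and immature arrays do not overlap at any of the 4 probes, which was a condition for naming them. The group means lie 7.25 log2 units apart at ILMN_3105563.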

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

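The count of changed probes stayed within 3457 to 4011 under every alternative apart from 2, and no called probe changed direction under any alternative run. The exceptions were the test without moderation, with 1226 changed, 577 higher and 649 lower (the cause was not tested), and the requirement of a 2-fold change, with 411, 273 and 138, which is stricter by construction. Of the 3982 called probes, 3929 were also called after quantile normalization, 3805 after cyclic loess and 3908 without a trend. Cyclic loess follows means of centred values, which are not signal levels, so its counts say nothing about an offset that depends on intensity. A shift of each array to a median of 0 moved nothing and says nothing about stability. The fit without a trend, the test without moderation, the replicate block and the 2-fold threshold also leave each log2 fold change as it was. They could not change a direction. The mean correlation within groups rose from 0.61 to 0.68 with cyclic loess, and the cause was not tested. The replicate block gave 3869 changed probes. A pairing by number was not seen, but 3 pairs of arrays cannot exclude one. Across the groups, deviations of same-numbered arrays correlated between -0.03 and 0.06, and those of other-numbered arrays between -0.06 and 0.06. Of the 6 arrays, 2 correlated best with the other group's array of their own number. Leaving out 1 array gave 3583 to 3851 changed probes, and 2932 remained called throughout. Of the 411 called probes of at least 2-fold, 392 remained called without each array with a trend and 411 without one. Filters on dim probes, other offsets, gene lists and other probes of a gene were not run, because the table holds no signal levels or gene names. Noise in the last decimal, leaving out arrays without a trend, and all alternatives for the correlation within groups and the 2-fold counts were chosen after seeing the data.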

Other observations

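The tests of the split between small and large changes were chosen after the result was seen, and the count over other splits of the arrays was planned. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 3982 probes, as the 1 split with a count that large, and the highest count of the other splits was 0. Each other split mixes arrays of both groups on both sides, so any group difference widens its spread and lowers its count. The 0 is therefore no measure of what chance alone would call.

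Called changes below 2-fold were mostly lower in aged follicles, apart from those under 0.2 on the log2 scale (61 higher, 47 lower), and those of 2-fold or more mostly higher. The tables argue against one array alone making the split, since without any of the 6 arrays the smaller of both shares was never under 59.9%. A uniform offset between the arrays of the 2 groups stays open for the changes below 2-fold. It would move all changes the same way. An offset that lowered the small changes could therefore not also make those of 2-fold or more mostly higher (273 higher, 138 lower). The median log2 difference over all probes was 0 where balancing the changes of 0.2 to 1 would need -0.036, but all 6 arrays have a median of 0, so this comparison was set by the alignment of the deposited values. An intensity-dependent offset left or made by the authors' normalization cannot be told apart from a difference between the age groups, because the centring removed the signal level. Cyclic loess left 59.4% of the calls below 2-fold lower, but without levels this decides nothing. A difference with age itself stays open and untested.

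The share of probes called rose with a probe's spread within the groups. Moderation lowers the standard errors of widely spread probes and raises those of the least spread, and its part in this rise was not tested. Among the tenth of probes with the largest spread, 1333 of 4529 probes (29.4%) were called, including 245 of the 411 called probes of at least 2-fold, against 187 of 4528 (4.13%) in the tenth with the smallest spread. The share called also differed by the leading digit of the probe number, from 7.60% of 17260 probes with a 1 to 9.42% of 25402 with a 2 and 10.7% of 2619 with a 3. The 4 probes that were not centred had medians over the arrays of 0.125 to 0.72, none of them was called, and 1 further probe was listed at 0 in every array.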
